A study of Arabidopsis thaliana with 8 samples.

How the data were processed

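Total RNA from developing seeds was labelled with biotin and hybridised to Affymetrix ATH1 arrays, 1 array per sample. Groups and replicate numbers were taken from the sample titles, which name 4 biological replicates of ttg1 and 4 of wild-type Ler. In the source labels both genotypes carry a suffix that runs from 6 to 9, read here as a running sample number. Wild-type Ler carries the same suffixes as ttg1, which argues against reading them as ttg1 alleles. The labels do not say what the suffix means. The labels do not say how the replicates were grown, so p-values measure the spread between these samples.

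The deposited values are RMA values per the submitters' processing notes, on a log2 scale, with no software version given. RMA corrects the background of each array, quantile normalizes the arrays and summarises the probes of each probe set. In the deposited log2 table each probe set has a median of 0 over the 8 arrays, within 5e-07, so the values had been centred per probe set. This was found from the values and is not described in the sources used here. The log2 base was taken from RMA, and a higher value was taken as more signal; neither was tested against scanner files, which were not used here. Because centring removes the level of each probe set, signal over background is unknown here and no probe set could be left out for being dim. The array medians over the tested probe sets were 7e-04, -0.0126, 0.0094 and 0.0279 in ttg1 replicates 1 to 4 and -0.0061, -8e-04, -0.0031 and -0.0024 in Ler replicates 1 to 4. No pair of arrays was alike: the SD of the difference between 2 arrays was at least 0.195.

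The difference between 3' and 5' control probe sets of actin, GAPDH and ubiquitin genes, a relative measure of RNA integrity, was 0.018 ± 0.061 in ttg1 and -0.074 ± 0.083 in Ler (SD, n = 4; exact two-sided permutation test, p = 0.171). Since each probe set was centred, these values compare the arrays with each other. They lie near 0 by construction and do not give the absolute integrity of the RNA.

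The table holds 22810 probe sets, of which 64 Affymetrix controls were left out of the tests. Genes were named from the platform annotation supplied with the values, which lists 1 gene for 13513 of the tested probe sets, several for 503 and none for 8730. A probe set without a listed gene is unnamed here, which does not mean that it has no gene. Gene IDs were matched to the RefSeq gene table of assembly TAIR10.1 for 13436 probe sets and 13286 genes, and no gene was named from a probe set with several genes. Of 251 genes on 16 lists fixed before the data were examined, 49 were measured by name.

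The difference ttg1 minus Ler was fitted per probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 arrays, no covariates, two-sided). The p-values were adjusted with the Benjamini-Hochberg method over 22746 probe sets, with a threshold of 0.05. Errors of log2 changes are limma's moderated standard errors. Gene lists with at least 3 measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over the 8 lists so tested; smaller lists are given as values. The planned choice of the probe set with the highest mean could not be applied to centred values, and each list gene had 1 probe set. The named genes were the 10 largest rises and 10 largest falls past the threshold without overlap between groups, up to 4 genes per list past the threshold, and the 2 genes with the smallest adjusted p where fewer than 2 passed. Of 12 pathway genes to be given whatever their values, DFR and BAN were measured by name. Other list genes given as values were chosen after their values were seen. Mean differences of a single measure over arrays were tested with exact two-sided permutation tests over 70 assignments, whose smallest possible p is 0.0286.

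The limma step was tested on simulated data with 22746 probe sets, 4 arrays per group and 200 changed probe sets. It recovered 20 of 50 probe sets changed by 0.5 on the log2 scale, 46 of 50 changed by 1, 50 of 50 changed by 2 and 50 of 50 changed by 4, and called 10 of 22546 unchanged ones. A simulated list of 8 genes shifted by -1 had a camera p of 1.89e-27, and 1 of 100 unshifted lists had an unadjusted p under 0.05. The simulated probe sets varied independently of each other. The simulation therefore does not show how well camera p-values hold where genes vary together.

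The alternatives tried were the replicate number as a block, quantile normalization, centring of each array on its median, robust eBayes, array weights, a test per probe set without moderated variances, a threshold of 0.01, values averaged per gene over probe sets with 1 gene, camera with an estimated correlation, fry, and the omission of each array in turn. The filter on dim probe sets and the intensity trend in eBayes were planned and not run, since both need levels. Added after seeing the data were the omission of ttg1 replicates 1 and 4 together and a covariate made from the mean of the 5 storage protein genes in each array.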

Results

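Gene expression was measured in developing Arabidopsis thaliana seeds of the ttg1 mutant and of the wild-type accession Landsberg erecta (Ler) on Affymetrix ATH1 arrays. TTG1 is a WD40-repeat protein that acts with MYB and bHLH transcription factors in the formation of trichomes, root epidermis, seed coat pigment and seed coat mucilage. Seeds from the globular to the walking-stick stage of embryo development were taken from the siliques, and each genotype was represented by 4 biological replicates on 1 array each. The number of arrays limits the precision of every value below. The values are on a log2 scale and give each probe set relative to its own median over the 8 arrays, so that they show differences between arrays and no absolute level. The array medians lay between -0.0126 in ttg1 replicate 2 and 0.0279 in ttg1 replicate 4.

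The comparison of ttg1 with Ler asks which transcripts of the developing seed depend on TTG1. In the values as deposited the widest falls were larger than the widest rises. The transcript of DFR (AT5G42800), the dihydroflavonol 4-reductase of anthocyanin and proanthocyanidin synthesis, was 127-fold lower in ttg1, with a log2 change of -6.99 ± 0.14 (SE, 4 arrays per group). BAN (AT1G61720), the anthocyanidin reductase that makes the proanthocyanidin precursors of the seed coat, was 86-fold lower (log2 change -6.43 ± 0.12). The widest fall was that of AT2G38900, which was 272-fold lower (log2 change -8.09 ± 0.13). The widest rise was that of WSD1 (AT5G37300), a wax ester synthase, which was 31.2-fold higher in ttg1 (log2 change 4.96 ± 0.33). In limma the Benjamini-Hochberg adjusted p was 1.53e-10 for DFR, 8.14e-11 for BAN, 5.79e-11 for AT2G38900 and 5.88e-06 for WSD1. Quantile normalization of the already centred values gave other folds. DFR was then 34.8-fold, BAN 25.7-fold and AT2G38900 74.9-fold lower and WSD1 65.1-fold higher, so that the widest fall and rise were close in size. That step gives all arrays a common distribution of centred values. Smaller falls with larger rises can come from the step itself, so these folds are no independent check of the deposited ones.

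Of 22746 probe sets tested with limma, 400 were higher and 900 were lower in ttg1 at an adjusted p under 0.05. A change of 2-fold or more was found for 40 of the higher and 263 of the lower probe sets, and 8 higher and 73 lower probe sets changed by 4-fold or more. Without Ler replicate 1, 2 or 3 the counts fell by over 1.5 times, to 233 higher and 535 lower, 164 higher and 509 lower, and 190 higher and 548 lower. Quantile normalization moved the higher share of the 2-fold changes from 13.2% to 25.7%, with 78 higher and 225 lower. Such a move can come from the step itself, which gives all arrays 1 distribution of centred values. In 3375 probe sets, 14.8% of those tested, all 4 ttg1 values lay on one side of all 4 Ler values, where chance assignment gives 2.86%. A single gene was named for 201 of the higher and 509 of the lower probe sets. TTG1 itself and many well-known seed coat genes had no named probe set and were not analysed here, so the mutated gene could not serve as a check of the sample labels.

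Besides DFR and BAN, the 10 named genes with the largest falls were AT2G38900, AT1G56100, AT1G62070, AT5G60630, AT3G49270, AT2G21430, AT1G09550 and AT2G14900. AT1G56100 was 200-fold lower (log2 change -7.65 ± 0.23), AT1G62070 was 107-fold lower (-6.74 ± 0.2) and AT5G60630 was 52.1-fold lower (-5.7 ± 0.15). AT3G49270, AT2G21430, AT1G09550 and AT2G14900 were 28.2-fold, 20.5-fold, 18.2-fold and 15-fold lower. With quantile normalization the fold of AT1G56100 was 61.4, of AT1G62070 37, of AT5G60630 18.7, of AT3G49270 12.7, of AT2G21430 10.1, of AT1G09550 8.7 and of AT2G14900 7.88, all still past the threshold. The adjusted p of these 8 genes in limma ranged from 5.79e-11 for AT2G38900 to 1.76e-05 for AT2G14900. Among probe sets with no gene listed, 267122_at was 196-fold lower (log2 change -7.62 ± 0.14) and 262119_s_at was 126-fold lower (-6.98 ± 0.1).

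**Figure D1:**
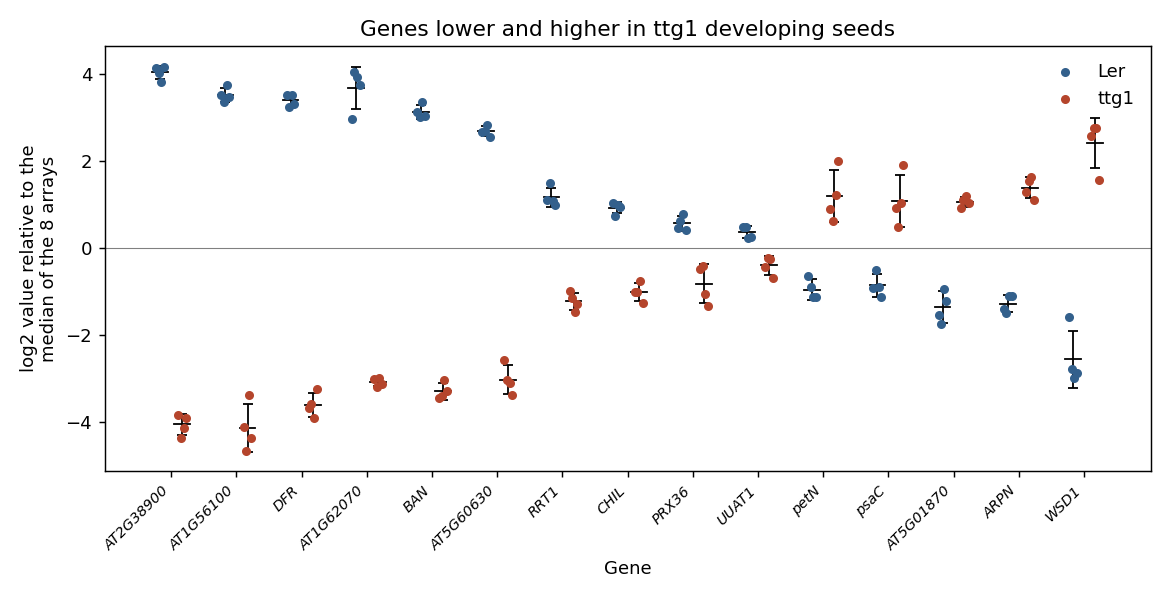
Log2 value of each array, relative to the probe set's median over the 8 arrays, for 15 of the named genes (x axis), with Ler in blue and ttg1 in red; points are single arrays, and the horizontal marks and bars give mean and SD of 4 arrays. In each gene all ttg1 points lie on one side of all Ler points, with the mean of DFR at 3.4 in Ler and -3.59 in ttg1, and that of WSD1 at -2.55 in Ler and 2.42 in ttg1.

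The 10 named genes with the largest rises included 3 genes of the plastid genome. The transcript of petN, a small subunit of the cytochrome b6f complex, was 4.4-fold higher (log2 change 2.14 ± 0.25), that of psaC, an iron-sulphur subunit of photosystem I, 3.84-fold (1.94 ± 0.25) and that of ndhD, a subunit of the NDH complex, 2.86-fold (1.52 ± 0.16). ARPN (AT2G02850), a plantacyanin, was 6.34-fold higher (2.66 ± 0.14), AT5G01870 5.37-fold (2.43 ± 0.16) and AT2G16630 3.41-fold (1.77 ± 0.11). The other 3 besides WSD1 are annotated as pseudogenes, and AT5G35880 was 5.73-fold, AT2G06390 3.37-fold and AT3G30510 2.99-fold higher. The adjusted p in limma ranged from 7.1e-07 for ARPN to 0.0144 for AT2G06390. Without Ler replicate 2 the adjusted p of AT2G06390 was 0.0524. With quantile normalization ARPN was 17.3-fold, AT5G35880 13.2-fold, AT5G01870 12.8-fold, petN 9.43-fold, psaC 6.24-fold and AT2G16630 6.13-fold higher. In petN, psaC, ndhD and the 3 pseudogenes the value was highest in ttg1 replicate 4, the array with the largest within-group deviation (SD over probe sets 0.245). Among probe sets with no gene listed, 259737_at was 9.43-fold higher (3.24 ± 0.21) and 249346_at 5.45-fold (2.45 ± 0.16).

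Of the late flavonoid list, which holds genes of proanthocyanidin synthesis, transport and oxidation, 3 of 9 genes were measured by name. DFR and BAN fell, and UGT80B1, a sterol glucosyltransferase, had a log2 change of -0.38 ± 0.1 and an adjusted p of 0.0515 in limma. Adjusted over the list alone, all 3 were lower. The list was shifted down against all other probe sets with an adjusted p of 1.69e-09 in limma's camera, and the shift held with an estimated correlation (adjusted p = 0.00625).

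Of the early flavonoid list, from the phenylpropanoid steps to flavonol glycosides, 3 of 16 genes were measured by name. CHIL (AT5G05270), a chalcone isomerase-like protein, fell 3.83-fold (log2 change -1.94 ± 0.11, adjusted p 1.89e-06 in limma). The flavonol glycosyltransferase genes UGT78D1 and UGT78D2 had log2 changes of -0.2 ± 0.12 and 0.07 ± 0.17 and did not pass the test. Adjusted over the list alone, 1 gene was lower. The list as a whole had a camera adjusted p of 0.035, with CHIL the only gene past the threshold, and adjusted p = 0.123 with an estimated correlation. It was 0.0912 without ttg1 replicate 3 and 0.0868 without Ler replicate 3.

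Of the mucilage list, 8 of 24 genes were measured by name, and 4 of them fell. RRT1 (AT5G15740), a rhamnosyltransferase of pectin synthesis, was 5.25-fold lower (log2 change -2.39 ± 0.13), the peroxidase gene PRX36 2.61-fold lower (-1.39 ± 0.19) and UUAT1, a transporter of UDP-uronic acids, 1.69-fold lower (-0.76 ± 0.12). MUCI21 was 1.35-fold lower (-0.43 ± 0.1, adjusted p 0.0337), and in 7 of 8 runs that each left out 1 array it did not pass the test, with log2 changes between -0.5 and -0.37. MUCI70, SBT1.7, DF1 and MUCI10 had log2 changes of -0.26, -0.11, 0 and 0.09 and did not pass. Adjusted over the list alone, 4 genes were lower. The camera adjusted p of the list was 0.000165, and adjusted p = 0.123 with an estimated correlation.

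Genes of storage and maturation did not pass the test. Of the storage protein list 5 of 13 genes were measured by name, of the oil list 4 of 23 and of the late embryogenesis list 7 of 15, with none higher or lower in limma or adjusted over the list alone. VCL2 and VCL, both vicilin-like proteins, had log2 changes of -0.37 ± 0.13 and -0.23 ± 0.19, FATA and FATB, acyl-ACP thioesterases, 0.14 ± 0.11 and -0.03 ± 0.13, and LEA42 and LEA4-2 -0.22 ± 0.08 and 0.17 ± 0.08. The sign of FATB changed under quantile normalization. The oil list had a median log2 change of -0.01 and a mean of 0.02, so its sign was not settled. The camera adjusted p was 0.561 for the storage protein list, 0.85 for the oil list and 0.666 for the late embryogenesis list. Several of these genes varied widely within both genotypes. The vicilin-like PAP85 had a value of 0.28 ± 1.36 in ttg1 and 0.28 ± 1.43 in Ler (SD, n = 4), with 2.17 in ttg1 replicate 4 and 2.28 in Ler replicate 4. The mean of the 5 storage protein genes was 0.094 ± 0.62 in ttg1 and 0.221 ± 0.716 in Ler (SD, n = 4), a difference of -0.128 with a 95% interval from -1.286 to 1.031 (exact two-sided permutation test, p = 0.714).

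**Figure D2:**
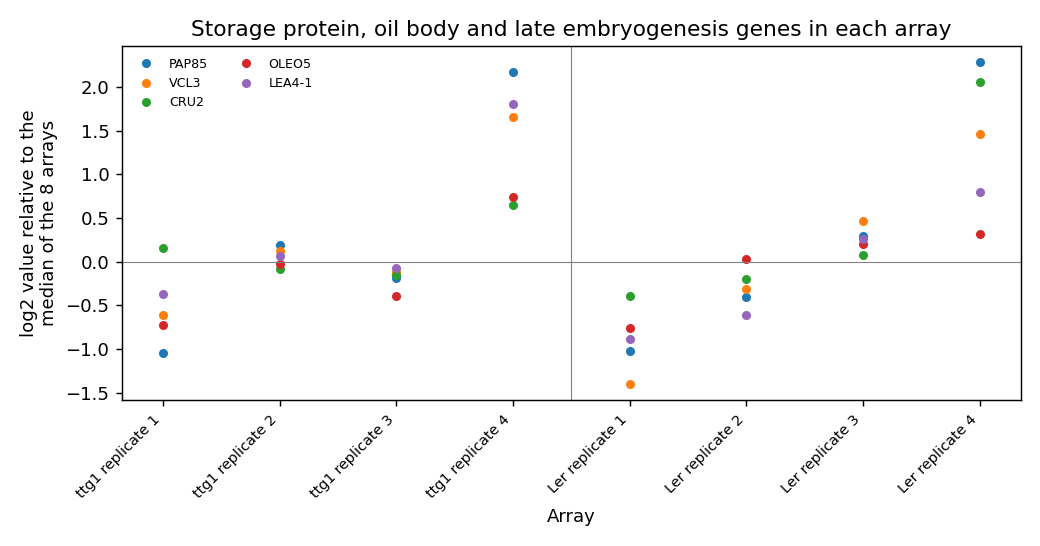
Log2 value, relative to the probe set's median over the 8 arrays, of the storage protein genes PAP85, VCL3 and CRU2, the oil body gene OLEO5 and the late embryogenesis gene LEA4-1 (colours) in each of the 8 arrays (x axis), with ttg1 on the left and Ler on the right of the vertical line. PAP85 ranged from -1.05 to 2.17 in ttg1 and from -1.02 to 2.28 in Ler, so the spread within each genotype exceeded the difference between them.

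Markers of other tissues were few among the named probe sets, and none passed the test over all genes in the fit of all 8 arrays without covariates. With the storage protein index as a covariate, added after seeing the data, YAB3 (log2 change 0.74, adjusted p 0.00241) and LHCB4.1 (log2 change 0.49, adjusted p 0.0121) passed. Both also passed with the replicate number as a block (adjusted p 0.0227 and 0.0366 in limma), though the labels give no pairing. Of the endosperm list 4 of 14 genes were measured by name, among them IKU2, a receptor kinase of endosperm growth, with a log2 change of 0.23 ± 0.12 and AGL28 with 0.09 ± 0.09, and the camera adjusted p of the list was 0.666. Of the silique wall list 2 of 12 genes were measured, YAB3 with a log2 change of 0.67 ± 0.23 and ALC with -0.47 ± 0.21; without ttg1 replicate 3 ALC passed the test over all genes (log2 change -0.67, adjusted p 0.0498). Adjusted over the list alone, YAB3 was higher (adjusted p 0.0272) and ALC was lower (adjusted p 0.049) in limma. That adjustment spans 2 genes only, and 5231 of the 22746 probe sets tested had an unadjusted p under 0.05 in limma. The ALC values overlapped between the groups. With array weights the log2 change of ALC was -0.17 (adjusted p 0.643 in limma), and without ttg1 replicates 1 and 4 together it was -0.12 (adjusted p 0.827 in limma). Of the photosynthesis list 2 of 15 genes were measured, LHCB4.1, a light-harvesting protein, with 0.43 ± 0.2 and RCA, the Rubisco activase, with 0.17 ± 0.17. YAB3, LHCB4.1 and RCA were all highest in ttg1 replicate 4, at 0.98, 0.83 and 0.64.

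The remaining lists gave no gene past the threshold, over all genes or adjusted over the list alone. Of the regulators list only TRY, a small MYB protein of trichome spacing, was measured by name out of 19 genes, and its log2 change was 0.11 ± 0.14. BZIP53 and EEL, 2 of 17 maturation regulators, had log2 changes of -0.09 ± 0.12 and 0.11 ± 0.19. The sugar transporters SWEET15 and SWEET11, 2 of 16 genes of the sugar and starch list, had -0.22 ± 0.12 and -0.2 ± 0.18. ZAT10 and COR15A, 2 of 17 stress response genes, had 0.03 ± 0.12 and 0.02 ± 0.11. The 4 of 11 reference genes measured by name served as a background, with log2 changes of -0.23 ± 0.08 for TIP41, 0.13 ± 0.09 for SAND, -0.04 ± 0.08 for UBC21 and 0.03 ± 0.09 for GAPC2, and a camera adjusted p of 0.708. The suberin and embryo patterning lists had no gene measured by name and were not analysed here.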

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

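The test of chance and the test of the chromosome segment were chosen before their results were seen; the test of seed age and both tests of the plastid genes were chosen only afterwards. The test of seed age took the place of an earlier one, with the storage protein index as a covariate, which decided nothing because the index differed little between the groups (-0.13); the thresholds of the test of a general plastid rise were reset after its value was seen.

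The number of changed genes was the first pattern weighed. Of the 35 splits of the 8 arrays into 4 and 4, 1 split, the real one, gave as many as 1300 called probe sets. The highest of the other splits called 0. For 2-fold changes the real split gave 303 and the highest other 0. A share of 1 in 35 is the smallest these splits can give, so chance is argued against at that level only. The other splits mix the genotypes, so genotype differences widen the spread within their groups and hold down their calls. With camera at the preset correlation, the real split also had the smallest p of the 35 for 2 lists, with the same limits. These were the late flavonoid list (camera p 2.11e-10, smallest other p 0.00142) and the mucilage list (camera p 4.13e-05, smallest other p 0.000531). With an estimated correlation the mucilage list did not pass (adjusted p = 0.123), and its splits were not run that way. A segment around TTG1 that differs between the lines would change its neighbours more often, but 9 of 177 probe sets within 200 genes of TTG1 (5.08%) and 689 of 13190 elsewhere (5.22%) were called, an odds ratio of 0.972 (95% interval 0.435 to 1.9, Fisher's exact test, one-sided p = 0.581). A shorter segment inside this window was not tested and is open, since AT5G24570 and AT5G24620, 5 and 11 genes from TTG1, were called. A difference in seed age was weighed through the storage protein index, and for 94.1% of the 303 probe sets with a 2-fold change the within-group slope on the index, times the widest group difference its 95% interval allows (1.29), stayed below 50% of their log2 change. The slopes entered without their own error, so the 94.1% has no margin. Replicate 4 had the highest index in both genotypes (1.001 in ttg1, 1.185 in Ler) and weighs heavily in the slopes. This test therefore does not settle the part of seed age. The loss of TTG1 function remains a hypothesis for these changes, and a part of them may follow seed age, which this index measures only through 5 genes.

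The plastid genome was the second pattern weighed. Of 69 plastid genome probe sets, 8 were higher (petN, psaC, ndhD, psbB, ndhG, psbN, ndhH and rpoC1) and 3 lower (petL, rbcL and psbJ) in ttg1 in limma, with none of these 11 signs changed by quantile normalization or by centring of the arrays. The median over all 69 was 0.09, with a 95% interval of -0.01 to 0.17 from a bootstrap over probe sets, which leaves out the spread between arrays. The 8 had a median of 1.29, but they were picked by being called higher. Their median is no fair measure for the whole set, so this comparison does not decide whether plastid transcripts rose in general. With quantile normalization this median over all 69 was 0.16. More plastid than nuclear protein-coding probe sets were called higher, 11.6% against 1.45% (Fisher's exact test, two-sided p = 8.9e-06). That test counts probe sets as independent, although they come from the same arrays and may vary together. Its p therefore does not measure the spread between samples. The plastid set was shifted up with an unadjusted camera p of 0.044, though camera p = 0.579 with an estimated correlation. Without ttg1 replicate 4, 8 of the 8 kept at least 50% of their log2 change. This decides little, since a called probe set can hardly lose that much when 1 of 4 arrays is left out. In the same fit 6 of the 8 still passed the threshold, which argues against an effect of replicate 4 alone for these 6. The other ones, ndhG and rpoC1, did not pass (adjusted p 0.069 and 0.0631 in limma). Of the 3 lower ones petL still passed there (adjusted p 0.0041 in limma), and rbcL (0.0781) and psbJ (0.0931) did not. An effect of the mutation on single plastid transcripts or on all of them is open. A difference in the green tissue of the samples is open as well. Of the nuclear photosynthesis list fixed beforehand only 2 genes were measured by name, and no wider set was tested. Neither passed in the main fit. With the replicate block LHCB4.1 passed (log2 change 0.43, adjusted p 0.0366 in limma) and RCA did not (0.17, adjusted p 0.564). Both were highest in ttg1 replicate 4.

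Single arrays stood apart from the other 3 of their group in 5 of 100 groups of 4 tested, where chance gives about 5. WSD1 was -1.57 in Ler replicate 1 against -2.98 to -2.77 in the others, and 1.57 in ttg1 replicate 4 against 2.57 to 2.76. YAB3 was 0.98 in ttg1 replicate 4 against 0.04 to 0.17, VCL was 0.52 in ttg1 replicate 4 against -0.29 to -0.26, and MUCI21 was 0.35 in Ler replicate 2 against 0.07 to 0.1.

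Among the 64 control probe sets, which were left out of the gene tests, the one for 5S ribosomal RNA was higher in all 4 ttg1 arrays than in all 4 Ler arrays, at 0.47 ± 0.23 against -0.38 ± 0.12 (SD, n = 4), a difference of 0.85 (exact two-sided permutation test, p = 0.0286, the smallest it can give). Of the 64, 2 were without overlap between groups where chance gives 1.8, and the other, a spike-in control for the bacterial gene dap, was lower in ttg1, at -0.36 ± 0.29 against 0.21 ± 0.13 (SD, n = 4), a difference of -0.56 (exact two-sided permutation test, p = 0.0286).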

How the results depend on the processing

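All 1300 calls kept their sign in each limma fit on all probe sets, and of these fits the one without Ler replicate 2 shared the fewest calls, 669. The test without moderated variances shared 532. With the replicate block, 687 probe sets were higher and 1283 lower in ttg1, and no list call changed; the labels give no pairing and the arrays were not treated as pairs, since the correlations of same-numbered arrays' deviations were 0.08, 0.03, -0.31 and 0.48 and 2 of 8 arrays correlated best with their own number. As a hint from the data, the storage protein index was lowest in replicate 1 (-0.359 in ttg1, -0.53 in Ler) and highest in replicate 4 (1.001 and 1.185) of both genotypes. With array weights 786 were higher. Without moderated variances 168 were higher and 409 lower, and at an adjusted p under 0.01 112 and 414. Over averaged 1-gene probe sets 195 were higher and 505 lower, 20 and 135 of them by 2-fold or more, as fewer genes were tested. Quantile normalization gave 78 higher by 2-fold or more. It moved the fold of 17 of the 25 named genes past the threshold by over 1.5 times. Of these, 10 falls were smaller and 7 rises larger, by up to 3.65 and 2.73 times. Quantile normalization gives all arrays 1 distribution of centred values, and smaller falls with larger rises can come from that step itself. No other limma fit moved a named fold that far. Leaving out 1 array gave 164 to 401 higher and 509 to 854 lower, and 36 to 46 and 221 to 290 by 2-fold or more; fewer arrays were fitted there. The last 2 alternatives were chosen after seeing the data: without ttg1 replicates 1 and 4 together 407 were higher and 619 lower, and with the storage protein index as a covariate 1544 were higher and 2030 lower, a count that rests on a covariate taken from the same arrays. YAB3 and LHCB4.1 passed with the block (adjusted p 0.0227 and 0.0366) and with the covariate (0.00241 and 0.0121), and VCL2 passed with array weights (0.0408). The early flavonoid list had an adjusted p of 0.123 with an estimated correlation, 0.0614 with the covariate and 0.0117 to 0.0912 over the runs without 1 array; the mucilage list had 0.123 with an estimated correlation and at most 0.00052 in those runs. Where not stated, the cause was not tested. The late flavonoid list passed in 17 of 17 alternatives, the mucilage list in 16 and the early flavonoid list in 13; the storage protein, oil, late embryogenesis, endosperm and reference lists passed in none. Averaging probe sets of a gene left each list gene at its value. The filter on dim probe sets and the intensity trend were not run, because the centred values hold no level; for the same reason signal over background is not known for any gene.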

Other observations

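The tests in this part were chosen only after the changed genes had been seen. The genes named here were picked from the calls after their values were seen. The UDP-glycosyltransferase gene UGT71B1 had a log2 change of -2.31 ± 0.13 in ttg1 (SE, adjusted p 1.1e-06 in limma), the glutathione transferase genes GSTU26 and GSTU15 had -2.2 ± 0.12 and -1.5 ± 0.26, and the beta-glucosidase genes BGLU45 and BGLU44 had -1.46 ± 0.21 and -1.26 ± 0.11. The carboxypeptidase-like gene scpl44 was higher (1.04 ± 0.15), as were the sugar transporter genes SWEET1 (0.58 ± 0.08) and SWEET13 (0.43 ± 0.11). By family, 4 of 47 UGT, 3 of 20 BGLU and 2 of 11 GSTU genes were lower and 2 of 14 SWEET genes were higher. Of 28 families grouped by symbol, 0 passed an adjusted p under 0.05 in camera, or with an estimated correlation; the smallest adjusted p was 0.0716, for the VPS and ATG families (median log2 changes -0.24 and -0.23), and 5 had an unadjusted p under 0.05. The adjusted p was 0.269 for UGT, 0.347 for BGLU, 0.508 for GSTU (median 0.03, test downward) and 0.282 for SWEET, so none of these families was shown to move as a group.

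Lower calls were missing among probe sets of genes annotated as pseudogenes or as transposon-derived. Of 989 such probe sets 13 were higher and 0 lower in ttg1 in limma, against 180 higher and 505 lower of 12374 nuclear protein-coding ones (Fisher's exact test on the direction of the calls, two-sided p = 4.09e-08). They were called less often in all, 1.31% against 5.54% (Fisher's exact test, two-sided p = 3.25e-11), while the share called higher was 1.31% against 1.45%, a difference that was not tested. The median log2 change was 0.07 against 0.02, and 76.3% against 54.2% of the probe sets had a change above 0. Without ttg1 replicate 4, 19 were higher and 0 lower, and with quantile normalization 32 and 0. The shift of the whole group had an unadjusted camera p of 5.15e-05, and p = 0.423 with an estimated correlation. The centred values hold no level, so it is not known whether these probe sets had signal that could fall. The Fisher test on direction therefore cannot tell a missing fall from a missing signal. Both Fisher tests on these probe sets count them as independent, although they come from the same arrays and may vary together. No explanation was tested.

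The closest called neighbours of TTG1 were AT5G24570, 5 genes away, with a log2 change of -2.07 ± 0.11, and AT5G24620, 11 genes away, with 0.83 ± 0.2. AT5G25930, 140 genes away, had -1.73 ± 0.11.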
